A study of Homo sapiens and Mus musculus with 28 samples.

How the data were processed

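The data are RNA sequencing libraries of the human colorectal cancer line DLD-1: 12 from a clone with degron-tagged GATA6, 6 from WT and KO cultures, and 10 from control and KO xenografts grown in athymic nude mice. Per the labels, RNA was extracted with a column kit and libraries were directional with poly-A selection. For each library the authors deposited 1 file of expected counts per gene and 1 file of TPM per gene. The submitters' processing notes name Trim Galore 0.6.10, STAR and RSEM and the genome build hg38, without stating the role of each tool, the versions of STAR and RSEM, the annotation release, the strand setting of the counting, or how mouse reads in the xenografts were handled. The labels give the organism of the xenograft libraries as mouse, while their files hold human gene identifiers, so all values are of human genes. Because the strand setting is unknown, values of genes that overlap another gene on the opposite strand, and of close paralogs, are less certain.

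The files fall into 3 annotation sets, of 60662 genes in the degron libraries, 60649 in the cultures and 62700 in the xenografts, with 60541 shared by the first pair, 60463 by cultures and xenografts and 60357 by all. Genes were joined by stable Ensembl identifier without its version, with pseudoautosomal copies on Y kept apart. Joining sets whose identifiers carry different versions departs from the plan for the comparison of cultures with xenografts, which had required identical identifiers. Symbols were looked up by identifier in a reference table, and coordinates and gene types came from a GENCODE annotation of the same build, whose release may differ from the one behind the files.

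Expected counts were rounded and analysed in R 4.3.3 with edgeR 4.0.16: filterByExpr over the groups of a fit, TMM scaling, robust quasi-likelihood fits and quasi-likelihood F tests. Adjusted p is Benjamini-Hochberg over all genes tested, with a threshold of 0.05, and counts of genes that also changed by a log2 of 1 or more are given beside it. The 12 degron libraries were fitted together with 4 groups, and the contrasts were 12 h against control, 72 h against control, 72 h against 12 h, washout against 12 h and washout against control. KO was compared with WT in cultures and with control in xenografts. The effects of 72 h and of culture knockout, and those of culture and xenograft knockout, were each compared by an interaction contrast in a fit of both systems. A standard error was taken as the size of the log2 fold change divided by the square root of F. For a gene with 0 counts in a group, the fold is a bound against a floor of 3 counts over the group, and with 1 to 3 counts the ratio of count rates is given with a 95% counting interval. Intervals and floors cover counting error only.

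A total of 39 gene lists with 735 members, covering lineage, signalling, cell cycle, metabolism, stress, RNA quality and other cell types, were fixed before the data were examined, as were the comparisons, tests and most alternatives. Lists with fewer than 5 tested genes were not tested as sets. Sets were tested with camera in limma 3.58.1 on voom values, with a preset correlation of 0.01 between genes, adjusted over the lists of a comparison. Every list called gave its p with an estimated correlation as well. Of the 82 calls with the preset correlation, 7 held with the estimated one: the cholesterol list after washout against 12 h and against control and in the comparison of 72 h with culture knockout, the G2/M list after washout against control, the G1/S list in KO cultures, WNT targets in the comparison of 72 h with culture knockout, and the presentation list in the comparison of xenografts with cultures. No list called had a median or mean opposite in sign to its test.

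The genes named were GATA6, then in each comparison the 10 highest and 10 lowest log2 fold changes among genes with adjusted p under 0.05, a mean log2 CPM of at least 1 and groups that did not overlap, then up to 4 members of each list with the smallest p. GATA6, LGR5, BMP4, CDX2, HNF4A, KRT20, MYC, MKI67, CYP1A1 and CYP1B1 were always given. The text names a selection of these. In the comparisons between systems, a few further genes were named because another comparison names them (among them INHBB, PMEPA1, CXCL5, ABCB1, ITGA9, ID2 and CDKN1A), chosen after their values were seen, as were the leukocyte genes set beside haemoglobin.

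Depth ran from 14569850 to 36500654 counts per library. The method was tested on simulated data with 200 changed genes in libraries of the same depth and spread. At a 2-fold change it recovered 80% of the changed genes at 12 h, 90% at 72 h, 88% in cultures, 78% in xenografts, and 60% and 52% in the comparisons of 72 h and of xenografts with cultures, with no wrong direction. Between 5 and 19 unchanged genes were called in each. Replicate numbers were checked for pairing of samples: same-number correlations of deviations from group means ran from -0.195 to 0.068, and 0 were over 0.1, so no pairing was used.

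Alternatives chosen beforehand were RLE and total-count scaling, no filter and a filter of at least 10 counts in every library of a group, DESeq2 1.42.0, limma-voom, limma on log2 of TPM plus 1, replicate number as a block, each replicate left out, fits of the compared pair of groups alone, host and epithelial list means as covariates in xenografts, a log2 threshold of 1, and for lists an estimated correlation and fry. Chosen after seeing the data were fits without the 72 h group, without the 4 libraries with haemoglobin, with mitochondrially encoded genes left out, and with the mitochondrial share as a covariate. Other splits of the samples were run for each count. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No library was left out of the main results, and TPM served in an alternative only.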

Results

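DLD-1 is an established human colorectal adenocarcinoma cell line, and GATA6 is a zinc-finger transcription factor of the gut endoderm lineage. The series title gives the subject as GATA6 control of gene expression and 3D genome organisation. In the expression data GATA6 was lowered by a degron and by knockout, the latter in cultures and in xenografts. In a clone whose GATA6 carries an auxin-inducible degron, a tag through which the plant hormone auxin triggers degradation of the protein, 12 libraries formed 4 groups of 3. These were control cells, cells given auxin (indole-3-acetic acid, 500 µM) for 12 h, cells given auxin for 12 h and then washed free of it for 24 h, and cells given auxin for 72 h. The labels give the control cells as auxin at 0 h, which was read as untreated. Cell cultures gave 3 wild-type (WT) libraries and 3 libraries from cells with CRISPR/Cas9 knockout of GATA6 (KO). Xenografts in the flank of athymic nude mice gave 5 control and 5 KO libraries.

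Total counts per library, in replicate order, were 20867266, 21239316 and 18296428 in degron control cells, 20034960, 25394470 and 18462679 at 12 h, 18674922, 18596791 and 19326940 after washout, and 24338937, 24732602 and 23618428 at 72 h. WT cultures held 22942556, 22604048 and 18408842 counts and KO cultures 23048891, 28585144 and 23434810. Control xenografts held 24646887, 36500654, 25043819, 20800254 and 20418444 counts, and KO xenografts 14569850, 26545459, 18487321, 18581163 and 18008922. The labels do not state that replicates were separate cultures or animals, so every p-value measures the spread between these samples. Levels are in CPM after TMM scaling, with the SD over the libraries of a group (n = 3 in cells, n = 5 in xenografts).

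GATA6 (ENSG00000141448; hg38 chromosome 18, 22169443 to 22202528, plus strand, protein-coding) was present in every library. Its transcript stood at 43.2, 49.8 and 46.9 CPM in degron control cells, 42.4, 45.1 and 48.1 CPM at 12 h, 51.3, 45.5 and 51.0 CPM after washout, and 31.5, 34.9 and 36.0 CPM at 72 h. Auxin acts on the protein, and the transcript at 12 h did not pass the test (log2 fold change -0.05, adjusted p = 0.784). At 72 h it fell by 0.45 on the log2 scale, from 46.6 ± 3.3 to 34.1 ± 2.4 CPM (adjusted p = 7.43e-06). The 3 WT cultures had 57.3, 73.7 and 91.7 CPM and the 3 KO cultures 25.2, 18.4 and 22.1 CPM, a fall of 3.39-fold (adjusted p = 0.00243). Control xenografts had 77.2, 80.2, 66.5, 67.3 and 74.9 CPM and KO xenografts 42.9, 34.9, 29.6, 38.8 and 28.98 CPM, a fall of 2.09-fold (adjusted p = 6.26e-07). The data hold no measurement of the protein.

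**Figure D1:**
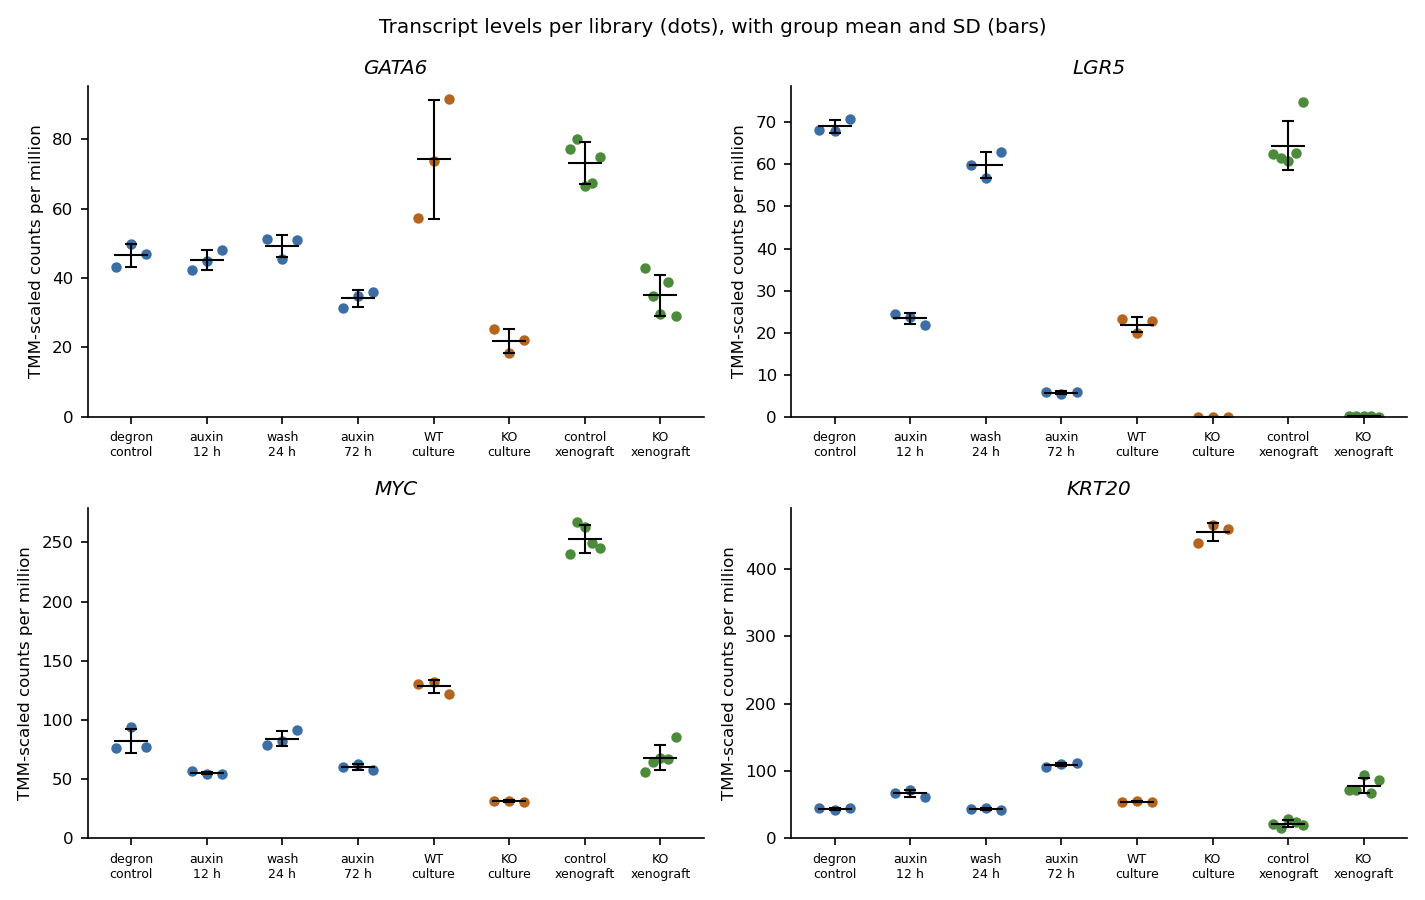
Levels of GATA6, LGR5, MYC and KRT20 (vertical axis, TMM-scaled CPM) in each of the 8 groups, with 1 dot per library and the group mean and SD as bars. LGR5 stood at 69.0 CPM in degron control cells, 23.4 CPM at 12 h, 59.8 CPM after washout and 5.72 CPM at 72 h, while KRT20 moved the other way, from 43.7 to 67.1, 43.6 and 110 CPM.

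The first question was which transcripts changed within 12 h of auxin. CLDN2, the claudin that forms a cation-permeable pore in tight junctions, fell 6.91-fold, from 48.0 ± 5.1 to 6.94 ± 0.21 CPM (log2 fold change -2.79, SE 0.086, adjusted p = 1.11e-17). LGR5, the R-spondin receptor that marks intestinal stem cells (ENSG00000139292; chromosome 12, 71439770 to 71586310, plus strand), fell 2.94-fold, from 69.0 ± 1.6 to 23.4 ± 1.3 CPM (adjusted p = 4.4e-15). OLR1, a lectin-like scavenger receptor, fell 2.48-fold to 131 ± 11 CPM. KRT20, a keratin of differentiated colonic epithelium (ENSG00000171431; chromosome 17, 40875941 to 40885227, minus strand), rose 1.54-fold to 67.1 ± 5.3 CPM (adjusted p = 1.47e-07).

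Among transcription factors at 12 h, the proto-oncogene MYC fell by 0.58 on the log2 scale, the basic helix-loop-helix factor TCF4 by 1.45, and the gut regulators HNF4A and CDX2 by 0.38 and 0.31. The alarmin cytokine IL33 fell 2.23-fold, the glucuronosyltransferase UGT1A6 2.03-fold and the tyrosine phosphatase PTPRR 3.15-fold. Among the genes that rose were the glucose transporter SLC2A12 (2.73-fold), the adhesion receptor ADGRF1 (2.5-fold), the repressor BACH2 (2.23-fold), the retinoic acid hydroxylase CYP26B1 (2.11-fold) and DACT1, a Dishevelled-binding protein of the WNT pathway (3.33-fold). MKI67, a marker of cycling cells (log2 fold change -0.38, adjusted p = 0.516), and CYP1A1, which aryl hydrocarbon receptor ligands such as indoles can induce (-0.28, adjusted p = 0.57), did not pass. CYP1B1 fell by 0.27, a call lost without control replicate 1 or 3 or 12 h replicate 2 or 3 (adjusted p = 0.0686 to 0.095).

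In the list of TGF-beta pathway genes, 4 of 16 rose and 0 fell (6 and 0 adjusted over the list alone), among them the ligands TGFB2 (0.73) and INHBB (0.68) and the receptor TGFBR2 (0.35); the list as a set was higher (adjusted p = 0.000889, and 0.0739 as adjusted p with an estimated correlation). In the BMP list, 4 of 16 rose and 0 fell (5 and 0 adjusted over the list alone): the homeobox gene MSX1 (0.85), ID2 (0.36), SMAD7 (0.22) and the ligand BMP4 (0.21). SMAD7 lost its call without any 1 of the 6 libraries compared (adjusted p = 0.0537 to 0.105). The set was higher (adjusted p = 0.000894; adjusted p = 0.0739 with an estimated correlation). In the MAPK list 4 of 22 rose, including PHLDA1 (0.47) and the EGFR ligand EREG (0.31), and 2 fell (6 and 2 adjusted over the list alone; adjusted p = 0.0095, and adjusted p = 0.0769 with an estimated correlation). In the angiogenesis list 3 of 11 fell and 0 rose (4 and 1 adjusted over the list alone). Those that fell were the receptor NRP1 (-0.56), THBS1 (-0.56), an inhibitor of angiogenesis, and VEGFA (-0.35). Tested as a set, the list had adjusted p = 0.0117, and adjusted p = 0.0896 with an estimated correlation. The WNT target list was not called as a set (5 of 19 rose and 2 fell, 7 and 3 adjusted over the list alone; adjusted p = 0.508). The other 3 lists called were lower with few or no single members called: ribosomal proteins (0 of 24, adjusted p = 0.00136), mitochondrially encoded transcripts (0 of 13, adjusted p = 0.0238) and glycolysis (1 up and 1 down of 18, adjusted p = 0.0481). Each had adjusted p = 0.816 with an estimated correlation, and the glycolysis median of -0.05 became 0.02 with TPM.

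In edgeR, 1037 of 14029 genes changed at 12 h, 567 higher and 470 lower, of which 47 changed by a log2 of 1 or more (16 higher and 31 lower). The share that was higher, 54.7%, became 66.9% with total-count scaling and 70.9% with TPM. The count was 606 without replicate 1 of the 12 h group and 623 without control replicate 2. Haemoglobin transcripts (HBA1, HBA2 and HBB) summed to 4897 and 1027 counts in 12 h replicates 2 and 3, against 5 or fewer in 12 h replicate 1 and the controls. Without these and the washout libraries that also held haemoglobin, 333 genes were called, an alternative chosen after seeing the data.

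After 72 h of auxin, 776 of the 1037 genes changed at 12 h were changed in the same direction, and many more genes differed from control. Both comparisons use the same control libraries. In 20 simulations without any change at most 2 genes were called in both. With no changed gene that overlap is small in advance, so it cannot show how many shared calls come from the shared controls. Over all genes 62.6% had the same sign, against 67.3% in the simulations. CLDN2 fell 37.2-fold, to 1.28 ± 0.051 CPM, LGR5 12.1-fold, to 5.72 ± 0.31 CPM (adjusted p = 5.94e-22 for each), the drug efflux pump ABCB1 12.7-fold, from 55.4 ± 4.3 to 4.36 ± 0.17 CPM, the integrin ITGA9 22.2-fold and the neutrophil-attracting chemokine CXCL5 8.6-fold, from 692 ± 64 to 80.5 ± 5.1 CPM. KRT20 rose 2.51-fold to 110 ± 2.7 CPM (adjusted p = 3.81e-15), and CDKN1A, which encodes the cell cycle inhibitor p21, rose 2.22-fold. MYC fell by 0.45, ASCL2, a transcription factor of intestinal stem cells, by 1.11 and CDX2 by 0.34, although CDX2 was higher by 0.21 with TPM. HNF4A did not pass (-0.10, adjusted p = 0.252).

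Further genes with high fold changes at 72 h included PTPRR (19.7-fold lower), UGT1A6 (7.67-fold lower), IL33 (6.24-fold lower) and the secreted glycoprotein AZGP1, which had 163 counts in control cells and 3 at 72 h (ratio 65, 95% counting interval 22 to 320; log2 -5.97, and -8.86 without 72 h replicate 1). Upward, DACT1 rose 14.2-fold, the inter-alpha-trypsin inhibitor ITIH2 10.1-fold, the podosome scaffold SH3PXD2A 9.98-fold, ADGRF1 9.41-fold, and the pro-apoptotic BH3-only gene BMF 7.58-fold. KLHL4 rose 92-fold, from 0.1 ± 0.045 to 9.93 ± 0.41 CPM. CYP1A1 rose 9.18-fold at 72 h, from 1.54 ± 0.22 to 14.2 ± 1.6 CPM (adjusted p = 2.89e-13), and CYP1B1 and TIPARP, also aryl hydrocarbon receptor targets, rose by a log2 of 1.00 and 0.91; that list as a set did not pass (6 of 9 rose and 2 fell; adjusted p = 0.111). MKI67 rose 1.7-fold (adjusted p = 0.0479), a call lost without control replicate 1 or 3 or any 1 of the 72 h libraries (adjusted p = 0.075 to 0.146).

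Gene groups of growth and metabolism were lower at 72 h relative to all genes, and 1 signalling group was higher. Of 24 ribosomal protein genes, 21 fell, including RPS2 (-1.08) and RPL8 (-0.48), and 1 rose (adjusted p = 4.53e-06). Of 21 nuclear-encoded respiratory chain genes, 17 fell, including UQCRFS1 (-0.91) and COX5A (-0.64), and 1 rose (adjusted p = 0.000262). Of 25 G1/S and DNA replication genes, 18 fell, including the thymidylate synthase TYMS (-0.62), and 2 rose, including the checkpoint adaptor CLSPN (0.63; adjusted p = 0.00192). Of 18 glycolysis genes, 12 fell, including ENO1 (-0.58), and 2 rose (adjusted p = 0.00885). Of 23 cholesterol synthesis genes, 14 fell, including DHCR7 (-0.80), and 1 rose (adjusted p = 0.0369). Of 16 TGF-beta pathway genes, 9 rose, including TGFB2 (1.83), the feedback regulator PMEPA1 (1.47) and INHBB (1.30), and 2 fell (adjusted p = 0.0444). The counts adjusted over the list alone were identical in these 6 lists, and each list had adjusted p = 0.395 with an estimated correlation. The G2/M list did not fall with the G1/S list. Of its 25 genes 10 rose and 3 fell (18 and 2 with total-count scaling), and it was not called as a set. The lists for RNA quality went both ways at 72 h. Of 12 nuclear noncoding RNAs and histone genes 3 rose and 3 fell (adjusted p = 0.96). The signal recognition particle RNA RN7SL1 rose from 21.2 ± 2.2 to 74.4 ± 6.2 CPM and its copy RN7SL2, outside the list, from 21.2 ± 2.4 to 94.6 ± 9.6 CPM, while RPPH1, the RNA of RNase P, fell by 1.98. Of 13 mitochondrially encoded transcripts 3 rose, including MT-ND6 (0.63), and 3 fell, including MT-CO3 (-0.88; adjusted p = 0.81), and together they took 3.16 to 3.86% of the counts in control cells and 3.92 to 4.06% at 72 h. WNT targets split, with AXIN2 (0.84) and LEF1 (0.84) among the 12 of 19 that rose and LGR5 and ASCL2 among the 5 that fell (12 and 6 adjusted over the list alone; adjusted p = 0.118). In the BMP list 6 of 16 rose, including SMAD7 (0.81), ID2 (0.65) and BMP4 (0.41), and 4 fell, including BAMBI (-0.71; 7 and 5 adjusted over the list alone; adjusted p = 0.407).

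At 72 h 8104 of 14029 genes (57.8%) changed, 3964 higher and 4140 lower, with 1069 by a log2 of 1 or more (673 higher and 396 lower). The 48.9% that were higher became 65% with total-count scaling and 65.2% with TPM, as the median of all genes shifted by 0.124 and 0.117, and the changes given are relative to that median; the cholesterol list then had 6 members higher and 7 lower with total counts. With TPM 3 ribosomal genes were higher and 13 lower, 5 and 10 in the respiratory chain, 3 and 7 in glycolysis and 3 and 6 in cholesterol synthesis. The 3 libraries at 72 h stood apart from the other 9 on the first principal component (48.4% of the variance), at 49.8 to 54.3 against -20.3 to -9.4. The series holds no untreated libraries of the same age and no cells without the degron that were given auxin. The degron comparisons alone therefore cannot separate an effect of auxin itself from loss of GATA6.

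The step from 12 h to 72 h was tested directly. ABCB1, which stood at 50.1 ± 2.9 CPM at 12 h, fell 11.5-fold, ITGA9 10.7-fold and LGR5 a further 4.09-fold, while AZGP1 went from 220 counts to 3 (ratio 83, 95% counting interval 28 to 408; log2 -6.28, and -9.17 without 72 h replicate 1). CYP1A1 rose 11.1-fold, BMF 6.97-fold, KLHL4 25.7-fold, CYP1B1 2.4-fold, MKI67 2.22-fold (adjusted p = 0.00897), KRT20 1.63-fold and BMP4 1.15-fold, and GATA6 itself fell by 0.40 (adjusted p = 3.46e-05). RN7SL2 and RN7SL1 rose 4.58-fold and 4.18-fold, MT-ND6 rose 1.53-fold and MT-CO3 fell 1.7-fold. HBA1 and HBA2 fell from 1798 and 1964 counts to 1 count each; without 12 h replicate 2, the library with most haemoglobin, or any 1 of the 72 h libraries, neither passed (adjusted p = 0.0943 to 0.155). In total 7769 genes changed, 3762 higher and 4007 lower (62.8% higher with total counts and 60.9% with TPM, against 48.4%), and 912 did so by a log2 of 1 or more. The 5 lists called were lower, as they were against control: ribosomal proteins (18 of 24 fell and 2 rose; adjusted p = 0.000383, and adjusted p = 0.549 with an estimated correlation), respiratory chain (17 of 21 and 1; 0.000853 and 0.491), G1/S (18 of 25 and 2; 0.00312 and 0.485), cholesterol (13 of 23 and 1; 0.014 and 0.479) and glycolysis (11 of 18 and 2, or 12 and 2 adjusted over the list alone; 0.0443 and 0.509). With TPM 10 respiratory chain genes fell and 4 rose, and 5 glycolysis genes fell and 2 rose.

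Whether the early changes reverted was examined by removing auxin after 12 h and waiting 24 h. The series holds no untreated cells described as washed. Effects of the wash and of time in culture therefore cannot be told apart from removal of auxin. CLDN2 rose 4.95-fold over its 12 h level, to 34.4 ± 1.3 CPM (adjusted p = 9.84e-16), LGR5 2.55-fold, to 59.8 ± 3 CPM (adjusted p = 1.18e-13), OLR1 2.91-fold, TCF4 2.53-fold, MYC 1.52-fold, to 84.2 ± 6.3 CPM (adjusted p = 4.54e-06), and CDX2 1.17-fold. KRT20 fell 1.54-fold, to 43.6 ± 1.9 CPM, SLC2A12 2.85-fold and BMP4 1.09-fold (adjusted p = 0.0478). The BMP4 call was lost without replicate 1 or 2 of either group (adjusted p = 0.111 to 0.218). HNF4A (0.20, adjusted p = 0.0651), MKI67 (0.61, adjusted p = 0.193), CYP1A1 (-0.25) and CYP1B1 (-0.08) did not pass, although without 12 h replicate 3 HNF4A and MKI67 did (adjusted p = 0.0175 and 0.0288). The YAP target ANKRD1 rose 2.65-fold, and the immediate early gene FOS, the calmodulin regulator PCP4 and the actin-severing protein SCIN fell 3.59-fold, 3.23-fold and 3.01-fold.

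The cholesterol synthesis list fell after washout, with 13 of 23 members lower and 0 higher (14 and 0 adjusted over the list alone; adjusted p = 5.5e-10, and 0.0052 as adjusted p with an estimated correlation). INSIG1 (-0.98), MSMO1 (-0.59), HMGCS1 (-0.48) and FDFT1 (-0.36) were among them, and the fatty acid desaturase SCD (-1.08) and the amino acid stress genes ASNS (-0.87) and SLC7A11 (-0.72) also fell. In the enterocyte list 4 of 8 fell, including the peptidase DPP4 (-1.29), ABCB1 (-0.89) and the cadherin CDH17 (-0.87), and 1 rose (adjusted p = 0.00134). In the NF-kB list 6 of 14 rose and 1 fell (9 and 1 adjusted over the list alone; adjusted p = 0.0016), and in the YAP and fetal-like list 5 of 17 rose and 1 fell (6 and 1; adjusted p = 0.0298). In the G2/M list 4 of 25 rose and 0 fell (adjusted p = 0.0262). Lower as sets were the stem cell list (6 of 13 fell and 1, LGR5, rose, 8 and 1 adjusted over the list alone; adjusted p = 0.0298), the hypoxia list (7 of 20 and 0; 0.0298), the MAPK list (6 of 22 and 2, or 7 and 2; 0.0321), the aryl hydrocarbon receptor list (4 of 9 and 1; 0.0262) and the BMP list (5 of 16 and 2; 0.0462). With an estimated correlation the adjusted p was 0.333 for the YAP list, 0.324 for the NF-kB list, 0.169 for the G2/M and BMP lists and 0.168 for the others.

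In all, 2444 genes changed after washout, 1300 higher and 1144 lower, of which 100 did so by a log2 of 1 or more (51 and 49). Washout replicates 1 and 3 held 227 and 2739 haemoglobin counts. The count was 1414 without washout replicate 3, 1566 without 12 h replicate 1, and 334 without the 4 libraries with haemoglobin, where 42.8% of the genes called were higher against 53.2%.

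**Figure D2:**
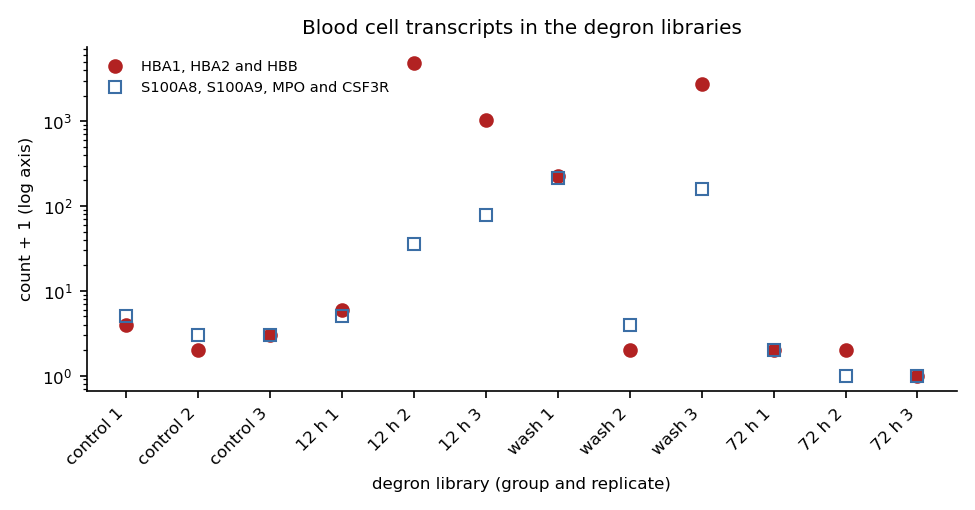
Summed counts plus 1 (vertical axis, log scale) of 3 haemoglobin genes (HBA1, HBA2 and HBB, red dots) and 4 leukocyte genes (S100A8, S100A9, MPO and CSF3R, open squares) in each degron library (horizontal axis). In 12 h replicates 2 and 3 and washout replicates 1 and 3 the haemoglobin sums ran from 227 to 4897 and the leukocyte sums from 35 to 211, while no other degron library held more than 5.

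Washed cells were also compared with control cells, which the labels do not describe as washed. MYC (0.03, adjusted p = 0.855), KRT20 (0.00, adjusted p = 0.985), GATA6 (0.08, adjusted p = 0.602), HNF4A (-0.19, adjusted p = 0.154), CDX2 (-0.08, adjusted p = 0.366), BMP4 (0.09), MKI67 (0.23) and CYP1A1 (-0.53) did not pass. LGR5 was 1.15-fold lower (adjusted p = 0.044), a call lost without control replicate 1 or 3 or washout replicate 1 or 2 (adjusted p = 0.0713 to 0.178). Also below control were CLDN2 (1.39-fold, adjusted p = 0.000121), ITGA9 (2.44-fold) and CYP1B1 (1.28-fold). KLHL4 was 7.79-fold higher, the carboxypeptidase CPA4 1.93-fold, MSX1 1.81-fold and the actin-binding caldesmon CALD1 1.78-fold higher, while FOS was 3.81-fold, DPP4 2.42-fold and the stress-induced mTOR inhibitor DDIT4 2.43-fold lower.

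The cholesterol list was also below control, with 12 of 23 members lower and 0 higher (17 and 0 adjusted over the list alone; adjusted p = 6.8e-18, and 0.000655 as adjusted p with an estimated correlation), as for INSIG1 (-0.76), HMGCS1 (-0.57), FDPS (-0.34) and SQLE (-0.34). The G2/M list was higher, with 5 of 25 members up and 0 down (9 and 0 adjusted over the list alone; adjusted p = 2.42e-06, and 0.0432 as adjusted p with an estimated correlation), including NDC80 (0.26) and UBE2C (0.25). Leaving out control replicate 2 or washout replicate 1 or 2 ended the NDC80 call (adjusted p = 0.0591 to 0.0736), and leaving out control replicate 1 or 3 or washout replicate 2 or 3 that of UBE2C (0.0502 to 0.0749). The other 11 lists called lost the call with an estimated correlation, where their adjusted p ran from 0.064 to 0.586. The YAP list (4 of 17 up and 1 down, 10 and 1 adjusted over the list alone; adjusted p = 6.14e-06, and 0.105 with an estimated correlation), the stem cell list (0 of 13 up and 5 down, 1 and 7 over the list alone; 0.000516 and 0.064) and the enterocyte list (1 of 8 up and 3 down; 0.00266 and 0.15) were among them. In all 701 genes differed from control, 370 higher and 331 lower, and 40 by a log2 of 1 or more (9 and 31). The count was 321 without control replicate 3, 353 without washout replicate 3, 458 in a fit of the 2 groups alone, and 179 without the libraries with haemoglobin.

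In cultures, knockout of GATA6 was compared with WT. LGR5 went from 1354 counts over the 3 WT libraries to 2 over the 3 KO libraries (ratio 795, 95% counting interval 220 to 6568). CLDN2 fell 97-fold, from 70.7 ± 2.3 to 0.724 ± 0.1 CPM (adjusted p = 3.34e-16), ABCB1 101-fold, ITGA9 188-fold, the trypsinogen PRSS2 142-fold, UGT1A6 90.1-fold, IL33 83.3-fold, the scaffold protein IQGAP2 79.1-fold and CXCL5 60.3-fold, from 379 ± 7.1 to 6.24 ± 0.63 CPM. KRT20 rose 8.33-fold, from 54.6 ± 0.46 to 455 ± 14 CPM. MYC (ENSG00000136997; chromosome 8, 127735434 to 127741434, plus strand) fell 4.09-fold, from 128 ± 5.4 to 31.4 ± 0.66 CPM (adjusted p = 1.84e-13), CDX2 1.87-fold and HNF4A 1.71-fold. Near the detection limit 1 library moved a size. ITGA9 stood at -7.55 and, without KO replicate 1, at -8.51. PRSS2 stood at -7.15 and, without KO replicate 2, at -7.82.

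Among the 10 genes that rose most in KO cultures, KRTAP3-1, a keratin-associated protein of hair, rose 104-fold, to 150 ± 1.5 CPM, and the hair keratins KRT34 67.6-fold and KRT81 45.7-fold. The phosphodiesterase PDE1C went from 3 to 818 counts (ratio 232, interval 79 to 1129) and the caveolar protein CAVIN2 from 2 to 416 (ratio 177, interval 49 to 1468). The calcineurin regulator RCAN2 rose 75.5-fold, the zinc-finger gene ZBED2 47.9-fold and the growth factor-like IGFL1 39.7-fold. KLHL4 was at least 275-fold lower (704 counts against 0, with a floor of 3 counts over the group), the reverse of its rise at 72 h in the degron clone. The kinase RPS6KA6 went from 474 counts to 2 (ratio 278, interval 77 to 2304). Leaving out 1 library moved CAVIN2 from 7.16 to 10.03 (WT replicate 3), PDE1C from 7.61 to 8.55 (WT replicate 3) or 7.02 (WT replicate 1) and RPS6KA6 from -7.94 to -7.34 (KO replicate 2). CYP1A1 rose 20.3-fold without auxin, to 3.39 ± 0.093 CPM, CYP1B1 1.15-fold (adjusted p = 0.0432) and TIPARP 1.48-fold. The CYP1B1 call was lost without WT replicate 1 or 2 or KO replicate 2 or 3 (adjusted p = 0.121 to 0.171). BMP4 (-0.10, adjusted p = 0.0798) and MKI67 (-0.24, adjusted p = 0.107) did not pass; BMP4 did without WT replicate 1 (adjusted p = 0.0178) and MKI67 without KO replicate 1 or 2 (adjusted p = 0.0094 and 0.0389).

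DNA replication genes fell in KO cultures, with 23 of 25 G1/S genes lower and 0 higher (adjusted p = 5.41e-11, and 0.0466 as adjusted p with an estimated correlation); the replicative helicase subunits MCM6, MCM4 and MCM2 fell by 1.07, 1.04 and 0.92. Of 23 cholesterol genes, 19 rose, including MSMO1 (1.05) and FDFT1 (0.70), and 0 fell (adjusted p = 4.63e-07). Of 11 MHC class I and II presentation genes, 10 rose, including HLA-B (2.71), the class I transactivator NLRC5 (1.72) and B2M (0.85), and 0 fell (adjusted p = 0.000256). Of 17 TGF-beta pathway genes, 12 rose, including PMEPA1 (1.57) and INHBB (1.45), and 2 fell (adjusted p = 0.00452). Of 18 WNT targets, 13 fell, including TNFRSF19 (-2.41), and 4 rose, including CD44 (1.57; adjusted p = 0.00599). With an estimated correlation these 4 lists had adjusted p = 0.224. In the BMP list 9 of 19 rose, with ID2 at 1.57, and 5 fell, with BMP2 at -1.55 (adjusted p = 0.145), and in the enterocyte list 3 of 9 rose, with CEACAM6 at 3.00, and 5 fell, with VIL1 at -2.45 (adjusted p = 0.551). CDKN1A rose by 1.31 and the stem cell gene CDCA7 fell by 2.09.

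Mitochondrially encoded transcripts took 6.23 to 7.11% of the counts in WT cultures and 4.12 to 4.65% in KO cultures. Of 13 such genes 13 fell, including MT-CO1 (-0.63) and MT-ND1 (-0.62; adjusted p = 9.69e-07, and adjusted p = 0.295 with an estimated correlation). Alongside them fell nuclear respiratory chain genes (16 of 21, with 0 up; adjusted p = 3.08e-05, and 0.224 with an estimated correlation), ribosomal proteins (19 of 24, with 1 up; 7.28e-05 and 0.344), G2/M genes (16 of 25, with 4 up; 0.00382 and 0.224) and glycolysis genes (12 of 19, with 4 up; 0.00924 and 0.297). Counts adjusted over the list alone were identical in each list called. In all 8123 of 13740 genes (59.1%) changed, 4173 higher and 3950 lower, with 1505 by a log2 of 1 or more (1049 and 456). The 51.4% that were higher became 62.2% with total counts and 74.4% with TPM, which shifted the median of all genes by 0.183. With TPM 6 ribosomal genes were lower and 2 higher (median -0.03 against -0.27), 9 and 5 in G2/M (-0.04 against -0.24), 7 and 1 in the respiratory chain (-0.12 against -0.31) and 8 and 6 in glycolysis (-0.15 against -0.41), so the number of lower members in these 4 lists depends on the scaling.

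In xenografts, KO tumours were compared with control tumours. LGR5 fell 460-fold, from 64.5 ± 5.9 to 0.137 ± 0.078 CPM (adjusted p = 5.97e-15), CLDN2 277-fold, from 104 ± 6.4 to 0.346 ± 0.19 CPM, ITGA9 173-fold, the laminin LAMA2 148-fold, ABCB1 147-fold, and KLHL4 at least 1075-fold (4271 counts against 0). MYC fell 3.71-fold, from 253 ± 12 to 68.2 ± 11 CPM (adjusted p = 3.11e-10), CDX2 1.3-fold (adjusted p = 0.00375) and HNF4A 1.23-fold (adjusted p = 0.00126). The intestinal homeobox gene CDX1 went from 263 counts to 1 (ratio 199, interval 35 to 7872; log2 -6.99, and -8.46 without KO replicate 2) and the muscarinic receptor CHRM3 from 625 to 2 (ratio 236, interval 65 to 1952). PRSS2 fell 231-fold, the enterocyte genes LGALS4 and VIL1 84.8-fold and 18.2-fold, DPP4 9.08-fold and the stem cell marker PROM1 54.9-fold. KRT20 rose 3.57-fold, from 22.0 ± 5.2 to 78.2 ± 11 CPM.

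Among the 10 genes that rose most in KO tumours, the hair keratin KRT31 was at least 450-fold higher (1019 counts against 0), the calmodulin-like CALML3 rose 950-fold, to 50.1 ± 25 CPM, the cornified envelope gene IVL 132-fold and KRT23 75.6-fold, and KRT38 went from 3 to 453 counts (ratio 200, interval 68 to 973; log2 7.26, and 8.19 without control replicate 3). CD4, known as a T helper cell coreceptor, went from 1 count to 894 (ratio 1184, interval 212 to 46822; log2 9.37, and 10.63 without control replicate 3). PTPRC, the pan-leukocyte marker CD45, had 0 counts in control tumours and 1 in KO tumours. The activin subunit INHBA rose 102-fold, to 20.6 ± 1.4 CPM, ADGRF1 95.3-fold, IGFL1 76.4-fold, TGFB2 5.93-fold, CDKN1A 5.16-fold, VIM, a mesenchymal intermediate filament, 6.57-fold and the WNT effector LEF1 3.31-fold. CYP1B1 did not pass (0.29, adjusted p = 0.0968) except without KO replicate 1 (adjusted p = 0.00913), and CYP1A1 was too low to be tested.

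Cell cycle genes fell in KO tumours: 23 of 25 G1/S genes, including CDT1 (-1.15), MCM4 (-0.95) and MCM7 (-0.95), and 24 of 25 G2/M genes, including BUB1 (-0.89), PLK1 (-0.85) and MKI67 (-0.70), were lower and 0 higher (25 of 25 in each adjusted over the list alone; adjusted p = 1.47e-07 and 1.94e-07). In the NF-kB and chemokine list 14 of 19 fell, including CXCL3 (-6.32), CXCL1 (-6.07), CXCL5 (-5.79) and CSF1 (-1.32), and 3 rose, with CXCL1 at -6.88 without KO replicate 3 (15 and 3 adjusted over the list alone; adjusted p = 0.000712). Of 23 cholesterol genes 16 fell, including HMGCS1 (-1.34) and INSIG1 (-0.83), and 2 rose (adjusted p = 0.0011). Of 11 presentation genes 7 fell, including NLRC5 (-1.41), PSMB9 (-1.32) and B2M (-0.87), and 0 rose (8 and 0 adjusted over the list alone; adjusted p = 0.00227). In the BMP list 11 of 18 rose, including ID2 (1.34), ID1 (1.33) and BMP4 (1.11), the last from 493 ± 39 to 1066 ± 130 CPM, and 4 fell (adjusted p = 0.0131). Mitochondrially encoded transcripts took 1.45 to 2.46% of the counts in control and 2.83 to 4.69% in KO tumours, and 11 of 13 rose, including MT-ND5 (1.34) and MT-CO2 (0.76; adjusted p = 0.000331), while 16 of 21 nuclear respiratory chain genes fell and 2 rose (adjusted p = 0.00216). With an estimated correlation each list called in xenografts had adjusted p = 0.735.

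The values are counts of human genes, and the labels do not state how mouse reads were handled. Of 5 fibroblast genes 1 rose, COL1A1 (1.62, adjusted p = 0.0147), and 1 fell, and of 5 endothelial genes 2 rose and 3 fell (adjusted p = 0.985 and 0.967). Of 3 tested NK and B cell markers 3 rose, including the granzymes GZMB (3.66, and 4.54 without control replicate 3) and GZMA (3.44), and of 3 skin markers 1 rose, KRT5 (3.68, and 4.68 without control replicate 2). In all 8413 of 14996 genes (56.1%) changed, 4199 higher and 4214 lower, with 1868 by a log2 of 1 or more (1151 and 717). With the mitochondrial share of each library as a covariate, chosen after seeing the data, 4997 genes were called. That share did not overlap between control and KO tumours, so this fit cannot separate it from knockout.

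**Figure D3:**
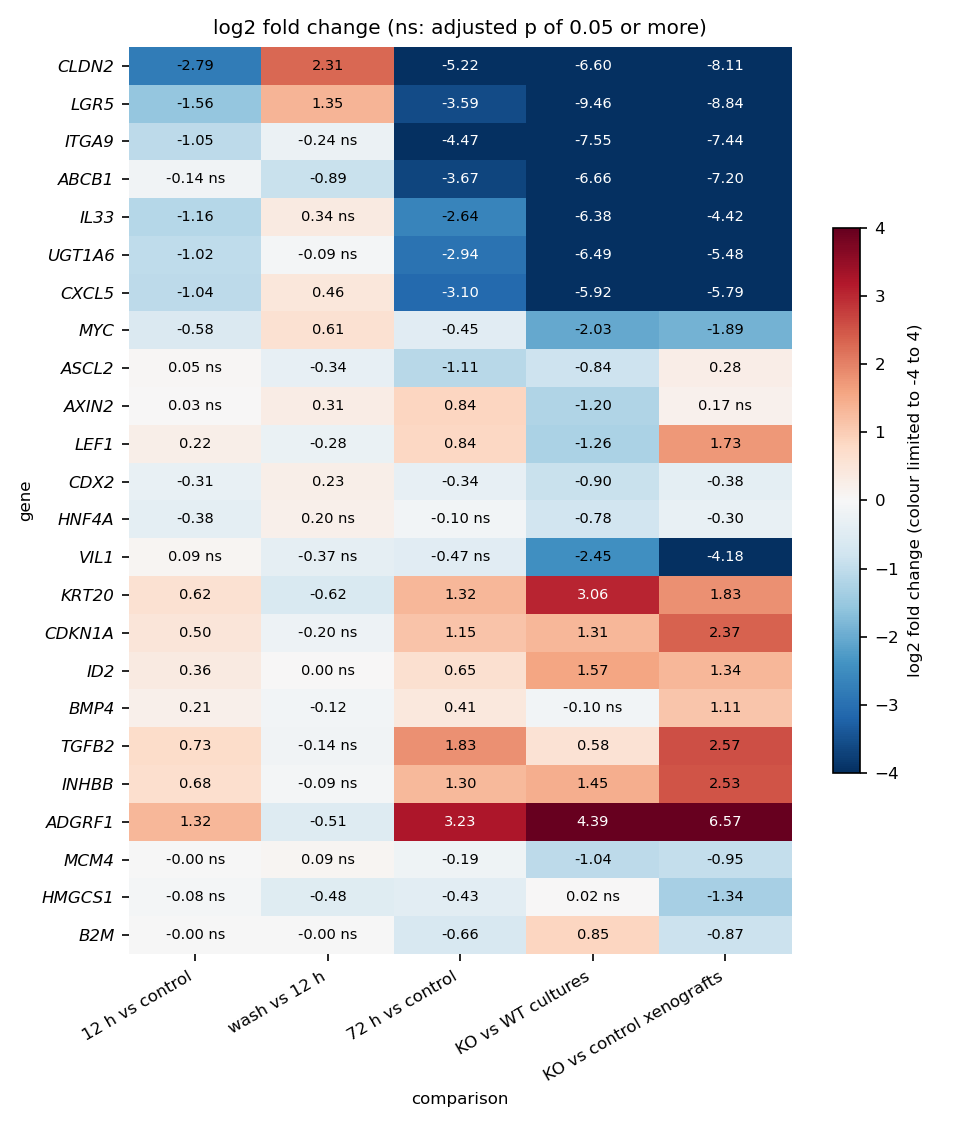
Log2 fold changes of 24 genes (vertical axis) in 5 comparisons (horizontal axis), with colour limited to the range from -4 to 4 and ns where the adjusted p was 0.05 or more. CLDN2 and LGR5 fell at 12 h (-2.79 and -1.56), rose on washout (2.31 and 1.35) and fell at 72 h (-5.22 and -3.59); the LGR5 value in KO cultures is fitted against 2 counts.

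The effect of 72 h of auxin was tested against that of knockout in cultures, each relative to its own control, and a positive difference here is a higher log2 change at 72 h. The loss of LGR5, CLDN2, ABCB1, ITGA9, IL33, UGT1A6 and CXCL5 was deeper in KO cultures, with differences of 5.87, 1.38, 2.99, 3.08, 3.74, 3.56 and 2.81, where the ITGA9 value was 4.04 without KO replicate 1 and the LGR5 value is fitted against 2 counts and had the other sign (-0.08) with TPM. MYC (1.59), CDX2 (0.56), TNFRSF19 (2.08) and IQGAP2 (5.01) also fell further in KO cultures, and GATA6 itself differed by 1.31. HNF4A (0.68), which fell in KO cultures, was not shown to change at 72 h. AXIN2 and LEF1 differed by 2.04 and 2.11, being higher at 72 h and lower in KO cultures. The imprinted noncoding RNA H19 differed by 6.70, with 34.0 ± 6.4 CPM in degron control cells, 52.7 ± 0.23 CPM at 72 h, 185 ± 21 CPM in WT and 2.72 ± 0.37 CPM in KO cultures, and the chloride channel CFTR by 4.68. KRT34 differed by -6.12, with a rise in KO cultures and 0.816 and 0.792 CPM in degron control cells and at 72 h. KRT20 (-1.73), ID2 (-0.92), KRTAP3-1 (-6.07) and KRT81 (-4.05) rose more in KO cultures, as did CYP1A1 (-1.15, adjusted p = 0.0211), which had the other sign with TPM (0.72) and did not pass without degron control replicate 1 or WT replicate 1 (adjusted p = 0.0546 and 0.151). INHBB (-0.15, adjusted p = 0.188), PMEPA1 (-0.10, adjusted p = 0.643) and CDKN1A (-0.16, adjusted p = 0.242) were not shown to differ.

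Of 19 WNT targets, 11 were higher in this difference and 2 lower (12 and 2 adjusted over the list alone; adjusted p = 2.42e-05, and 0.0382 as adjusted p with an estimated correlation). Of 23 cholesterol genes, 22 were lower and 0 higher, including DHCR7 (-1.09), FDPS (-1.01) and CYP51A1 (-0.88; adjusted p = 3.94e-13, and 0.0345 as adjusted p with an estimated correlation). G1/S genes (17 of 25 higher and 0 lower, 19 and 1 adjusted over the list alone; adjusted p = 3.29e-07, and 0.0826 with an estimated correlation) and G2/M genes (16 of 25 and 3, or 18 and 3; 8.81e-06 and 0.102) had higher changes at 72 h, and MKI67 differed by 1.01. Presentation genes were lower (0 of 12 higher and 9 lower; 4.54e-05 and 0.118), with HLA-B at -2.22 and B2M at -1.51. Mitochondrially encoded transcripts (11 of 13 higher, 0 lower; 1.87e-06 and 0.346), endoderm transcription factors (9 of 19 and 0; 0.00804 and 0.135) and aryl hydrocarbon receptor targets (7 of 11 and 1; 0.00686 and 0.135) were higher, with CYP1B1 at 0.79 and BMP4 at 0.51, and the NF-kB list was lower (1 of 15 higher and 8 lower; 0.0215 and 0.424). In all 6398 of 14536 genes differed, 3258 higher and 3140 lower (50.9% higher, and 39.9% with TPM), and 1239 by a log2 of 1 or more. The systems differ in clone, in duration, in exposure to auxin and in the set of gene models in their files, which this test cannot separate.

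The effect of knockout was also tested between xenografts and cultures, a positive difference being a higher log2 change in xenografts. LGR5 (0.65, adjusted p = 0.578), MYC (0.16, adjusted p = 0.409), CXCL5 (0.14, adjusted p = 0.757), ITGA9 (0.14, adjusted p = 0.911), ABCB1 (-0.52, adjusted p = 0.485), ID2 (-0.21, adjusted p = 0.321), MKI67 (-0.45, adjusted p = 0.239) and CYP1B1 (0.11, adjusted p = 0.744) were not shown to differ, although with TPM LGR5 stood at -1.44 and ITGA9 at -0.46. CLDN2 (-1.50) and VIL1 (-1.71) fell further in xenografts, and KRT20 rose less (-1.21). GATA6 (0.71, adjusted p = 0.018), CDX2 (0.54) and HNF4A (0.49) fell less in xenografts. TNFRSF19 (3.06), LEF1 (3.00), AXIN2 (1.38), BMP4 (1.23), CDKN1A (1.07), the adhesion molecule CADM1 (5.28), the semaphorin SEMA5A (6.37), IVL (5.90) and KRT23 (6.30) had higher changes in xenografts, while the acute phase gene SAA1 (-6.06), CXCL1 (-6.85) and PIGR, the receptor for polymeric antibodies (-7.11), had lower ones. CYP1A1 stood at -6.88, at -5.65 without control xenograft replicate 3, which held 42 of its few counts in xenografts, and at -7.51 without KO xenograft replicate 4. CXCL1 stood at -6.26 without WT replicate 2 and at -7.65 without KO xenograft replicate 3. Single libraries decided some of these calls: GATA6 without WT replicate 3 or KO culture replicate 2 (adjusted p = 0.0587 and 0.0583), CDKN1A without any 1 of the culture libraries but KO replicate 3 (adjusted p = 0.0509 to 0.0699), KRT23 without WT replicate 2 (2.18, adjusted p = 0.891) and PIGR without KO culture replicate 1 (-6.15, adjusted p = 0.223). Without WT replicate 1 these last values were 6.90 and -11.24.

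Presentation genes differed between the settings, with 10 of 12 lower in xenografts and 0 higher, including NLRC5 (-3.12), PSMB9 (-1.85) and B2M (-1.71; adjusted p = 2.05e-10, and 0.0466 as adjusted p with an estimated correlation). Cholesterol genes (21 of 23 lower, 1 higher; adjusted p = 7.05e-15), including INSIG1 (-1.72) and HMGCS1 (-1.34), the NF-kB list (16 of 20 lower and 0 higher, 17 and 1 adjusted over the list alone; 2.99e-08) and the interferon list (9 of 19 and 1, or 10 and 3; 0.00668) were also lower. Mitochondrially encoded transcripts (12 of 13 higher and 0 lower, or 13 and 0; 1.33e-11), including MT-ND3 (2.04) and MT-CO2 (1.46), and WNT targets (9 of 19 higher and 2 lower, or 11 and 2; 0.000924) were higher. These 5 lists had adjusted p = 0.268 with an estimated correlation. G2/M genes (10 of 25 lower, 0 higher, or 11 and 0; 2.21e-05) and the MAPK list (12 of 22 lower, 3 higher; 0.000952) had adjusted p = 0.623 with it, and ribosomal proteins (3 of 24 higher, 0 lower; 0.00797) had 0.732, with a median of 0.19 that became -0.11 with TPM. In all 4328 of 16021 genes differed, 2024 higher and 2304 lower, and 1302 by a log2 of 1 or more. The 46.8% that were higher became 32.5% with total counts and 17.5% with TPM, which moved the median of all genes by -0.263.

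Shared genes were counted across the systems. Of 13211 genes tested in both, 5135 changed at 72 h of auxin and in KO cultures, 3982 of them (77.5%) in the same direction, 1870 higher and 2112 lower, where 2316 would be so if the calls were independent. With a log2 of 1 or more in both, 308 of 332 (92.8%) had the same direction. Across genes, which are not independent replicates, Pearson's r was 0.408 and Spearman's rho 0.417. KO cultures and KO xenografts shared 5257 changed genes, 4482 (85.3%) in the same direction against 2278 for independent calls, with r = 0.617 across genes. Both KO sets are labelled sgGATA6, so they may share differences from their controls that are not due to GATA6. Independent calls are then a low reference. At 72 h of auxin and in KO xenografts 3504 of 4765 shared genes (73.5%) had the same direction. Of the genes changed at 12 h, 702 of 833 (84.3%) that also changed in KO cultures had the same direction.

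**Figure D4:**
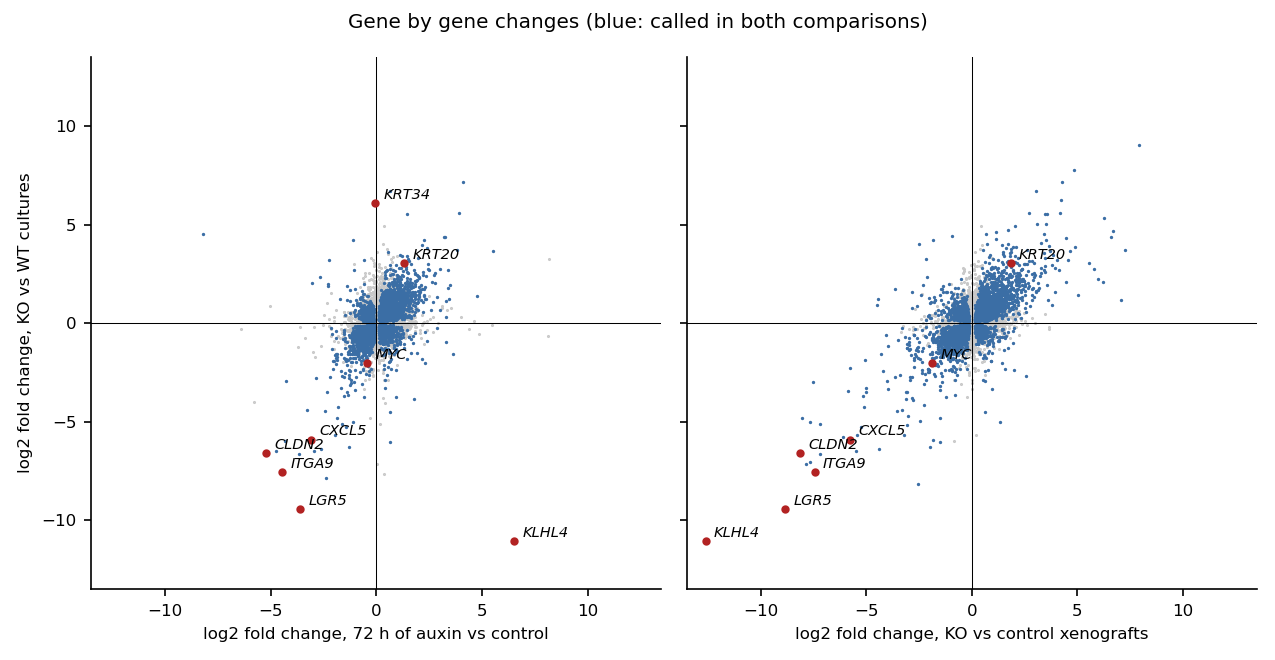
Log2 fold change of each gene in KO against WT cultures (vertical axes) plotted against its change at 72 h of auxin (left) and in KO xenografts (right), with genes called in both comparisons in blue and 8 named genes (7 on the right) in red. Of the blue genes 77.5% on the left and 85.3% on the right lie in the quadrants of equal sign; KLHL4, with 0 counts in the KO groups, is drawn at its fitted value.

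In the same direction at 72 h of auxin, in KO cultures and in KO xenografts, 2495 of 12764 genes changed, 1070 higher and 1425 lower. Independent calls would give 666, although the KO sets may not be independent of each other. A log2 of 1 or more in all 3 held for 163 genes, 111 higher and 52 lower, among them LGR5, CLDN2, ITGA9, ABCB1, CXCL5, IL33, UGT1A6, PTPRR and TCF4 on the lower side and ADGRF1 on the higher. Of the 2495, 435 also changed the same way at 12 h, and 286 of those moved back significantly on washout. Of the 1037 genes changed at 12 h, 669 moved back after washout, 8 moved further, 117 still differed from control in the same direction and 35 in the opposite one. These 12 h comparisons share the 12 h or control libraries, so part of the moves back is built in. In 20 simulations without any change 33.7% of all genes had the same sign at 12 h and on washout, against 28.2% observed. At most 1 gene was called in both there, against 677, but with no changed gene few calls were possible. That count cannot show how many of the 677 are built in. Of the 8104 genes changed at 72 h, 55.8% (95% Clopper-Pearson interval 54.7 to 56.9) had the opposite sign between 12 h and washout, which has no libraries in common with the 72 h comparison. The other splits of the washout and 12 h libraries gave 35.3 to 64.7% for these genes, so chance was not excluded. Among the 1069 with a log2 of 1 or more the share was 52% (interval 49 to 55), and among the 2495 it was 63.6% (61.7 to 65.5). Other splits were not run for either of these sets. Genes are not independent, so the intervals are too narrow as statements about all genes.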

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

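The tests of explanations and the counts of other splits in this part were chosen after the result was seen, while the tests of differences between systems were planned.

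About 8 times as many genes changed at 72 h of auxin as at 12 h (8104 against 1037), and the 72 h libraries stood apart from the other 9. Depth was tested by thinning each degron library to 18296410 counts, which left 7852 genes at 72 h and 1003 at 12 h, a ratio of 7.83, and argues against depth. Of the 5135 genes also changed in KO cultures, 3982 (77.5%) had the same direction, where independent calls would give 2316. That is more than a batch moving each gene independently would give. Genes do not move independently, and a batch could move groups of genes the same way as knockout. The agreement therefore cannot exclude a library batch of the 72 h group. The agreement does not decide for single genes either, nor for the 1153 that went the opposite way. The series holds no untreated libraries of that age and no cells without the degron that were given auxin. For the 2715 genes changed at 72 h and tested but not called in KO cultures, batch, time in culture, auxin itself and loss of GATA6 therefore cannot be told apart. Among these genes, the signal recognition particle RNAs RN7SL1 and RN7SL2 rose by 1.81 and 2.15 at 72 h and stood at 0.11 and -0.12 in KO cultures (adjusted p = 0.889 and 0.839).

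The 10 genes with the highest change in KO xenografts included 5 known from epidermis and hair (CALML3, IVL, KRT31, KRT38 and KRT23), which raises the question of host skin. KRT1 and KRT5, abundant in skin, were also higher in KO tumours (9 to 37 counts against 0 to 5, and 42 to 169 against 1 to 31), while KRT14, also abundant there, had 8 to 18 against 0 to 578. In each KO tumour the 5 genes together held at least 9.4 times the counts of these 3 keratins. How mouse reads were handled is not known, and the share of them counted in a human gene may differ by gene. The ratio therefore cannot decide whether host skin was the main source of the sum. CALML3 made up most of that sum in KO replicates 1 to 4 (582 of 822, 2480 of 3662, 728 of 1249 and 923 of 1437 counts). Nor does the ratio speak for each of the 5 genes. The rise of KRT1 and KRT5 stays open as well. KRT10, also abundant in skin, was left out of the ratio of the 5 genes to keratins because control tumours held it too. It had 382 to 980 counts there, against 361 to 739 in KO tumours (0.31, adjusted p = 0.202 in the edgeR test). With all of it counted as skin the ratio was 1.46 to 4.1, which again rested largely on CALML3. In KO replicate 1 KRT10 had 488 counts, and 582 of the 822 counts of the 5 genes were CALML3. Of the 10 genes, 5 were higher in KO cultures, which hold no host tissue (KRT38, IVL, ADGRF1, IGFL1 and INHBA), and the other 5 were too low there to be tested; with those counted as not higher, 5 of 10 against 26.7% of all genes tested in xenografts gave p = 0.0989 (exact binomial test, one-sided), so expression shared with cultures stays open for the 10 as a set.

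Haemoglobin transcripts were present in 4 of 12 degron libraries. Each of the 4 also held leukocyte transcripts (S100A8, S100A9, MPO and CSF3R), the lowest count being 35 against at most 4 in the other degron libraries, so RNA of blood or bone marrow cells in these libraries is a candidate explanation; the labels describe no such cells. MPO alone is not specific, since cultures with at most 8 haemoglobin counts held 10 to 212 of it, whereas S100A8 had 7 to 28 counts in the 4 libraries and 0 in the other degron and the culture libraries. The ratio of haemoglobin to leukocyte counts ran from 1.08 to 140 between the 4 libraries (7.57 to 163 with MPO left out), so a single mixture of constant composition would not give all of them. A response to GATA6 degradation is argued against by the 4 auxin libraries without the pattern, whose highest haemoglobin count was 5.

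Single xenograft libraries stood apart from their group in 11 of 131 groups tested. Each value is the gap to the nearest library as a share of the range, which is always 1 where a group holds a single count. Chance gives about 5 percent for normally distributed values. Counts near 0 are not so distributed, and the genes share the same libraries, so the 11 do not show an excess. LGR5 was 75.4 CPM in control replicate 5 against 61.6 to 63.2 (0.886), and PRSS2 149 CPM in control replicate 2 against 42.7 to 68.6 (0.757). In KO replicate 2, CALML3 was 92.9 CPM against 31.5 to 46.9 (0.749) and CD4 12.5 against 7.2 to 8.43 (0.77), and the 1 count of CDX1 among KO tumours fell in it (1). The 1 count of CD4 among control tumours fell in control replicate 3 (1), which also had 1.03 CPM of GZMB against 0.0831 to 0.337 (0.731). INHBA was 0.0986 CPM in control replicate 5 against 0.205 to 0.241 (0.749), IGFL1 31.2 in KO replicate 5 against 7.56 to 13.7 (0.739), CXCL5 24.3 in KO replicate 3 against 13 to 16 (0.732) and HNF4G 0.905 in KO replicate 1 against 1.39 to 1.57 (0.723).

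Of 46 named differences between systems tested, 29 passed. Between 72 h of auxin and culture knockout the log2 differences were 1.31 for GATA6, 1.38 for CLDN2, 5.87 for LGR5, 2.99 for ABCB1, 3.08 for ITGA9, 2.81 for CXCL5, -1.73 for KRT20, 1.59 for MYC, 0.56 for CDX2, 0.68 for HNF4A, 3.56 for UGT1A6, 3.74 for IL33, -1.15 for CYP1A1, 0.79 for CYP1B1, 0.34 for TIPARP, 1.01 for MKI67, -0.92 for ID2 and 0.51 for BMP4. That of KLHL4, 17.59, is a fitted value against a group at 0 counts and no measure of size. Between xenograft and culture knockout they were 0.71 for GATA6, -1.5 for CLDN2, -1.21 for KRT20, 0.54 for CDX2, 0.49 for HNF4A, 1.23 for BMP4, -3.12 for NLRC5, -1.71 for B2M, -1.71 for VIL1 and 1.07 for CDKN1A.

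In other splits of the 6 samples of each degron or culture comparison, 1 split of 10 (the real one) gave the highest number of genes: 1037 at 12 h (highest other 65), 8104 at 72 h (1), 7769 from 12 h to 72 h (0), 2444 on washout (0), 701 for washout against control (1) and 8123 in KO cultures (0). For lists the real and highest other counts were 7 and 8 at 12 h (2 splits of 10 with as many), 6 and 5 at 72 h, 5 and 6 from 12 h to 72 h (2 of 10), 10 and 8 on washout, 13 and 7 for washout against control, and 11 and 10 in KO cultures (1 of 10 in each of the other 4). With 10 splits a share under 0.05 cannot be reached. In xenografts the real split gave 8413 genes and the highest other 1, so chance was excluded (1 of 100 splits), but other splits called up to 15 lists against 11 for the real one (23 of 100 called as many), and chance was not excluded for their number. For the difference of 72 h from culture knockout chance was not excluded for lists (10 and 12; 9 of 100), and neither was it for the difference of xenografts from cultures (9 and 13; 19 of 100). For genes the first gave 6398 and the highest other split 3971 (1 of 100 with as many), and the second 4328 and 5917 (2 of 100). The splits that called genes, 22 of 100 in the first and 12 of 100 in the second, kept the real groups of 1 system, whose effect then stood alone, and the other 78 and 88 called 0, so these shares say nothing about chance and the 5917 reflects the structure of the samples. For the 3982 genes changed in the same direction at 72 h and in KO cultures the highest other split gave 0 (1 of 100), but other splits of either system called at most 1 gene, so this count says nothing about a shared direction. For the reverting share, meaning 72 h genes with the opposite sign on washout (55.8%), the washout and 12 h libraries were split in 20 ways. The share was as high in 9 of them, the real one included, with the highest other at 64.7%, so chance was not excluded. With 20 splits a share under 0.05 could not have been reached in any case.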

How the results depend on the processing

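In this part the fits without the 4 libraries with haemoglobin, without the 72 h group, without mitochondrially encoded genes and with the mitochondrial share as a covariate were chosen only after the result was seen. Of 6562 values of 360 named results under alternatives, 6413 kept direction and side of the threshold, 128 lost the call, 16 gained one and 5 reversed, all with TPM: CDX2 at 72 h (0.21), LGR5 and CYP1A1 in the comparison of 72 h with culture knockout (-0.08 and 0.72), and LGR5 and ITGA9 in that of xenografts with cultures (-1.44 and -0.46); the cause was not tested. HBA1, HBA2 and HBB passed at 12 h only in DESeq2 (adjusted p = 0.0368, 0.0036 and 0.026).

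With TPM the genes changed numbered 357 at 12 h, 1123 on washout and 281 for washout against control, and those with a log2 of 1 or more 9, 22 and 13, 432 at 72 h, 309 from 12 h to 72 h, 795 in KO cultures, 849 in xenografts and 745 between 72 h and culture knockout; the cause was not tested. With no filter, which adds genes with low counts, those with a log2 of 1 or more were 124 at 12 h, 156 on washout, 78 for washout against control and 2976 in xenografts, and with DESeq2 51 on washout. Without the libraries with haemoglobin, which leaves 1 library at 12 h and 1 after washout, assumed to vary like the others, counts were 333 at 12 h, 334 on washout (49 by a log2 of 1) and 179 for washout against control (25), and fewer samples explain part of the drop. A fit of the pair alone gave 458 for washout against control, and the cause was not tested. The mitochondrial covariate gave 4997 in xenografts. There the mitochondrial share did not overlap between control and KO tumours and cannot be separated from knockout. A log2 of 1 in both, a stricter rule, left 308 shared genes at 72 h and in KO cultures, and the reverting share was 52%. Estimated correlations called 7 lists in place of 82. The directional test of fry, which asks whether a list moves one way without comparing it with other genes, called 173.

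With 1 replicate left out, genes changed ran from 606 (without 12 h replicate 1; 623 without control replicate 2) to 1170 at 12 h, 7257 to 7685 at 72 h, 6723 to 7650 from 12 h to 72 h, 1414 (without washout replicate 3; 1566 without 12 h replicate 1) to 2266 on washout, 321 (without control replicate 3; 353 without washout replicate 3) to 896 for washout against control, 7373 to 8041 in KO cultures, 7579 to 8496 in xenografts, 5811 to 6501 and 3627 to 4611 in the comparisons of 72 h and of xenografts with cultures, and 3655 to 3910 for the overlap; the reverting share ran from 50.7% (without 12 h replicate 3) to 58.7%. Replicate blocks gave 1202, 8185, 7844, 2642, 816, 7723, 8045, 5925 and 3848 genes in the same order of comparisons. Depth limits genes near the filter, and a change under 2-fold may go unseen there, since simulated 1.5-fold changes were recovered for 38 to 78% of genes, fewest between xenografts and cultures.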

Other observations

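No test in this part was chosen after its result was seen, although the members named as examples were. In KO cultures 11 of 19 CTCF, cohesin and loop regulator genes fell and 1 rose, where 59.1% of all genes changed (adjusted p = 0.00924, and adjusted p = 0.224 with an estimated correlation), including the cohesin release factor WAPL (-0.69), the cohesin subunits SMC3 (-0.53) and SMC1A (-0.46), and CTCF itself (-0.47). Under other scalings of the KO cultures this list was less one-sided, with 4 higher and 10 lower by total counts, and 4 higher and 6 lower with TPM, where its median was -0.02 against -0.24. In KO xenografts 13 of 19 fell and 2 rose (15 and 2 adjusted over the list alone; adjusted p = 0.014, and adjusted p = 0.735 with an estimated correlation), with WAPL at -0.94, RAD21 at -0.51 and SMC3 at -0.51, while LDB1, an adaptor of GATA factor complexes, rose by 0.40. In the comparison of 72 h of auxin with KO cultures, 11 of 19 had the higher change at 72 h and 0 the lower (12 and 0 adjusted over the list alone; adjusted p = 0.000636, and adjusted p = 0.118 with an estimated correlation), with differences of 0.87 for SMC3, 0.79 for WAPL, 0.70 for SMC1A and 0.64 for CTCF. In xenografts the gut endoderm transcription factor list was lower as well (12 of 20 fell and 4 rose; adjusted p = 0.0493, and adjusted p = 0.735 with an estimated correlation): HNF4G fell by 2.19 and ESRRA by 0.86, while GATA2 rose by 1.75. Of 12 nuclear noncoding RNAs and histone genes 3 rose, including H2BC4 (3.24) and H1-2 (2.37), and 1 fell (adjusted p = 0.0493, and adjusted p = 0.735 with an estimated correlation). Of 9 secretory lineage genes 5 fell, with CREB3L1 at least 30-fold lower (118 counts against 0), and 2 rose, with AGR2 at 1.43 (3 and 5 adjusted over the list alone; adjusted p = 0.388).

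After washout, in the aryl hydrocarbon receptor list 4 of 9 were below control, including UGT1A6 (-1.11) and NQO1 (-0.42), and 0 higher (4 and 1 adjusted over the list alone; adjusted p = 0.00131, and adjusted p = 0.0823 with an estimated correlation). In the fatty acid list 4 of 22 were lower, with SCD at -1.03, and 1 higher (8 and 2; 0.0225 and 0.105), and in the stress response list 5 of 20 were lower, with ASNS at -0.82 and SLC7A11 at -0.79, and 1 higher (6 and 2; 0.0366 and 0.185). The TGF-beta list was above control, with 3 of 16 higher, PMEPA1 (0.78), TGFB2 (0.59) and INHBB (0.59), and 0 lower (6 and 2; 0.0366 and 0.185), as did the NF-kB list, with 2 of 14 higher, including LIF (0.77), and 1 lower (6 and 2; 0.0366 and 0.502). Mitochondrially encoded transcripts (0 of 13 called; 2.6e-05 and 0.437), ribosomal proteins (0 of 24; 0.00291 and 0.586) and nuclear RNAs (0 of 12 higher, 1 lower; 0.0363 and 0.222) were also lower as sets. At 72 h of auxin, interferon response genes (10 of 18 rose and 3 fell, 11 and 3 over the list alone; adjusted p = 0.156), with IFIT1 at 1.31 and OAS1 at 0.89, and p53 targets (9 of 20 rose and 1 fell; adjusted p = 0.176), with MDM2 at 0.34, were not called as sets, nor was the stress response list (9 of 20 rose and 4 fell; adjusted p = 0.176), with DDIT3 at 1.59.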
